A study of Homo sapiens with 9 samples.

How the data were processed

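RNA was sequenced from MCF-7 tumorspheres in 3 groups of 3 libraries, with total RNA prepared as TruSeq libraries and read on an Illumina HiSeq instrument, per the labels' protocols and the series' design text. FastQC 0.11.2, TopHat2 2.0.13 and Cufflinks 2.2.1 and the genome build hg19 are named in the submitters' processing notes, without their settings. The annotation, any strand setting and any filter are not given in the sources used here. The deposited table holds 1 value per gene symbol and library, taken here as FPKM, fragment numbers scaled to transcript length and to the mapped fragments of a library. The file header states no unit. FPKM was inferred from Cufflinks in the submitters' processing notes and from values that are not whole and whose sums differ between libraries. The upper quartile over all genes lay between 12.06 and 12.31 in every library and the sums between 720224 and 1194363. Whether a scaling between libraries was applied before deposit is not given in the sources used here, and no further scaling was used.

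The table has 23614 symbols, 26 of which had been turned into dates or numbers and were kept as they stood. Rows of microRNAs, snoRNAs and snRNAs held 34.5% to 55.4% of each library's FPKM sum. In 55 rows, all of such short RNAs, some libraries were at 0 and the others averaged at least 20 FPKM, so a 0 there can be a failed estimate. The 13 mitochondrially encoded transcripts of the gene lists had no row in the table, and 12 other list genes were listed at 0 in every library. Genes are named by the table's symbols, some of them older ones (NOV, ERO1L, FAM101A, DDX58). No coordinates are printed, because the reference table used for gene order, assembly GRCh38.p14, is of another build. Genes that share reads with near copies, such as histone, keratin and CEACAM family members, are uncertain, and without a stated strand setting overlapping genes are too.

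FPKM values keep no absolute depth, and none was stated. Relative depth was recovered from genes below 0.3 FPKM, where values step by whole fragments. The ratio of the steps between libraries gave a mean relative depth of 0.96 in LXSN, 0.98 in wtPELP1 and 1.85 in cytoPELP1, with LXSN replicate 1 set to 1. No counting intervals could be given. Read counts were not available from the table, so tests made for counts were not used; the design fixed before the data were examined had named limma for this case.

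Values were analysed as log2(FPKM + 1) with limma 3.58.1 (R 4.3.3), with an intensity trend, in 1 model of all 9 libraries with a mean per group and 6 residual degrees of freedom. Genes with a group mean of at least 1 FPKM in at least 1 group were tested, 12032 in number, with Benjamini-Hochberg adjustment and an adjusted p of 0.05. Fold changes on this scale understate the change of low genes. Gene lists, 28 with 540 different genes, some of them in more than 1 list, were fixed before the data were examined. Of these genes 523 were in the table. The lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. A list needed at least 3 tested members, which 25 lists had. Members were also counted with p-values adjusted over the list alone. Calls by camera with the preset correlation that the estimated correlation does not keep are given with both p-values. PELP1 was also tested with an exact two-sided permutation test.

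Genes were named by a rule set before the data were examined. It took PELP1, PFKFB3, PFKFB4, NCOA1, NCOA3, ESR1, PGR, HIF1A and EPAS1 in every comparison. It added the 10 largest rises and 10 largest falls among called genes of at least 5 FPKM in the higher group whose libraries did not overlap, without uncharacterised loci, small RNAs and pseudogenes. It also added up to 2 rising and 2 falling called members of each described list, and the 5 genes called in both comparisons against LXSN with the largest smaller change in each direction. Genes named outside it are marked where they appear.

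Replicate numbers are shared between groups in the labels. Whether same-numbered libraries deviate together was checked before the fits were compared. For LXSN and wtPELP1 the correlations of their deviations were 0.18, 0.14 and 0.23, each above 0.1, so the numbers pair these libraries by the rule used here, and a fit with the replicate number as a block stands beside the unblocked one as an alternative. This pairing comes from the data and not from the labels. Deviations from a group mean cancel out within the group, so these correlations are not independent. No chance level was computed for the cut of 0.1, so the pairing may be accidental. Between LXSN and cytoPELP1 they were 0, 0.10 and 0.11 and between wtPELP1 and cytoPELP1 -0.11, -0.02 and -0.06.

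The model was tested on simulated data with 12032 genes, with 100 changed by a log2 change of 0.5 and 100 by 1. Changes were planted only in genes above a set mean level. Noise was drawn independently with the model's own fitted spread, the same in all groups. The shares thus do not cover changes of the lowest genes, differences in depth or pairing of libraries. In the simulated cytoPELP1 to LXSN comparison 91% of log2 changes of 0.5 and 100% of log2 changes of 1 were recovered, with 3.5% false among the calls. In the simulated wtPELP1 to LXSN comparison the shares were 89% and 100% with 3.1% false, and in the simulated cytoPELP1 to wtPELP1 comparison 87% and 100% with 3.1% false. Other settings tried were a pseudocount of 0.1, no filter on low values, quantile normalization, median scaling, a replicate block, only the 6 libraries compared, a log2 fold threshold of 1, an adjusted p of 0.01 and leaving out each library. Chosen after seeing the data were the removal of trends on transcript length and GC content (loess with span 0.5, for the 10753 tested genes, 89.4%, with such values), only genes of at least 50 FPKM, no short RNA rows, and the replicate block together with the trend removal, with genes of at least 50 FPKM or with only the 6 libraries of LXSN and wtPELP1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.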

Results

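RNA sequencing measured gene expression in tumorspheres of MCF-7, an estrogen receptor positive human breast cancer cell line. The cells carried the empty retroviral vector LXSN, wild-type PELP1 (wtPELP1) or a cytoplasmic form of PELP1 (cytoPELP1), with 3 libraries in each of the 3 groups. PELP1 is a coregulator of steroid receptors that is found mainly in the nucleus. The spheres had grown for 6 days in serum-free suspension culture before RNA was taken. The series concerns metabolic kinases regulated by PELP1 and SRC-3, the p160 coactivator encoded by NCOA3. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

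The table held FPKM values for 23614 gene symbols, of which 5334 were listed at 0 in every library. The number of sequenced fragments was not given. Relative depth, read from the smallest steps between low values, was 0.86 to 1.02 in LXSN, 0.95 to 1.03 in wtPELP1 and 1.51 to 2.04 in cytoPELP1, with LXSN replicate 1 set to 1. The labels name no sequencing run or batch. If the deeper cytoPELP1 libraries formed a batch of their own, that batch and the group cannot be told apart in any comparison with cytoPELP1. Correlations of log2(FPKM + 1) ranged from 0.9649 to 0.9851 between libraries of a group and from 0.9531 to 0.9752 between groups. The first principal component, with 25.2% of the variance, set the cytoPELP1 libraries apart from the other 6.

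PELP1 itself was examined first as a check of the labels. Its level was 6.39 ± 0.212 FPKM in LXSN, 263.6 ± 26.5 FPKM in wtPELP1 and 266.4 ± 26.9 FPKM in cytoPELP1 (mean ± SD, n = 3 per group). Against LXSN this was 41.2 times as much in wtPELP1 and 41.7 times as much in cytoPELP1, a log2 fold change of 5.16 ± 0.08 and 5.17 ± 0.08 (SE). The exact two-sided permutation test gave p = 0.1 for both, the smallest value that 3 libraries against 3 allow. PELP1 in cytoPELP1 and wtPELP1 differed by a log2 change of 0.02, less than the spread between replicates (limma adjusted p = 0.917, exact permutation p = 0.9). The table has 1 value per symbol, so PELP1 values hold transcripts of the introduced and the resident gene together.

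**Figure D1:**
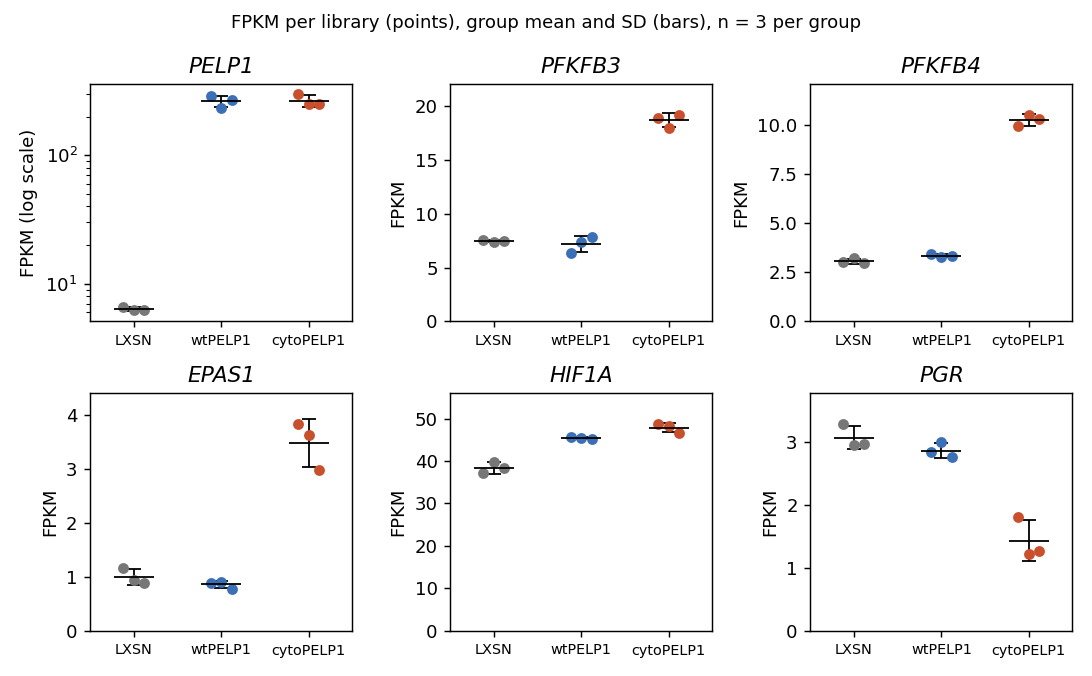
FPKM of PELP1 (log axis), PFKFB3, PFKFB4, EPAS1, HIF1A and PGR in the 9 libraries (points) by group, with the group mean and SD (horizontal lines and error bars, n = 3). PELP1 lies near 264 to 266 FPKM in both PELP1 groups and at 6.39 FPKM in LXSN, while PFKFB3, PFKFB4 and EPAS1 stand higher in cytoPELP1 alone and PGR lower.

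The comparison of cytoPELP1 with LXSN asked which transcripts differed in cells with PELP1 in the cytoplasm. PFKFB3 and PFKFB4, the bifunctional enzymes that make and degrade the glycolytic activator fructose 2,6-bisphosphate, both rose. PFKFB3 went from 7.49 ± 0.0567 to 18.7 ± 0.656 FPKM and PFKFB4 from 3.08 ± 0.129 to 10.3 ± 0.301 FPKM (mean ± SD, n = 3), log2 fold changes of 1.22 and 1.46 (limma adjusted p = 1.94e-06 and 2.75e-07). EPAS1, which encodes the hypoxia-inducible factor HIF-2 alpha, rose from 0.999 to 3.48 FPKM, and HIF1A from 38.4 to 47.9 FPKM (log2 fold change 0.31). PGR, the progesterone receptor gene and a classical estrogen target, fell from 3.07 to 1.43 FPKM (log2 fold change -0.75, limma adjusted p = 0.00043). The coactivator genes NCOA1 and NCOA3 and the estrogen receptor gene ESR1 did not pass the test, with log2 fold changes of 0, 0.12 and -0.02.

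Hypoxia response genes moved together in cytoPELP1. Of 23 tested members, 22 rose against LXSN and 0 fell, and the count adjusted over the list alone was also 22 (median log2 fold change 0.93, camera adjusted p = 4.1e-19, and 0.0064 with an estimated correlation). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 1.73 on the log2 scale. Of 18 glycolysis genes 13 rose and 0 fell, among them LDHA, lactate dehydrogenase A, with a log2 fold change of 1.32 and GAPDH with 0.84. For glycolysis 14 rose and 2 fell when adjusted over the list alone (camera adjusted p = 8.8e-08, but adjusted p = 0.21 with an estimated correlation). Of 16 genes in the list of PFKFB and other metabolic kinases 8 rose and 0 fell, and adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 0.0011, and 0.038 with an estimated correlation). That list was chosen with the subject of the series in view and shares PFKFB3 and PFKFB4 with other lists, so its direction is not independent evidence.

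Cell cycle and interferon genes were also higher in cytoPELP1 than in LXSN. Of 30 cell cycle genes 22 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 8.7e-13, and 0.0039 with an estimated correlation). MKI67, the gene of the proliferation marker Ki-67, rose by 1.37 and TOP2A, topoisomerase II alpha, by 1.32 on the log2 scale. Of 26 type I interferon response genes 20 rose and 1 fell, again with the same counts adjusted over the list alone (camera adjusted p = 3e-10, and 0.0039 with an estimated correlation), led by MX2 with 1.00 and IFI44L with 0.88. Of 19 p53 target genes 1 rose and 11 fell, counts that also held adjusted over the list alone (camera adjusted p = 0.0012, and 0.038 with an estimated correlation). The cell cycle inhibitor CDKN1A had a log2 fold change of -0.96 and the stress cytokine GDF15 one of -1.20, while BTG2 rose by 0.67.

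Lists of lipid, serine and mitochondrial metabolism passed camera in cytoPELP1 with the preset correlation and not with an estimated one. Of 15 genes of fatty acid synthesis and storage 9 rose and 1 fell, both also adjusted over the list alone, with FASN, fatty acid synthase, at a log2 fold change of 0.57 and DGAT1 at -0.57 (camera adjusted p = 0.0058, but adjusted p = 0.14 with an estimated correlation). Of 14 pentose phosphate and serine pathway genes 6 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0058, but adjusted p = 0.41 with an estimated correlation). PSAT1 and PHGDH, enzymes of serine synthesis, rose by 0.48 and 0.39. Of 32 nuclear genes of oxidative phosphorylation 0 rose and 8 fell, also adjusted over the list alone, UQCRH at -0.44 and NDUFB3 at -0.42 (camera adjusted p = 0.014, but adjusted p = 0.71 with an estimated correlation). The call of that list also ended without cytoPELP1 replicate 1 (adjusted p = 0.17) and with quantile normalization (adjusted p = 0.074).

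Estrogen response genes went both ways in cytoPELP1. Of 27 tested members 8 rose and 11 fell, with the same counts adjusted over the list alone, and camera gave adjusted p = 0.75. TFF1, a secreted trefoil peptide and classical estrogen target, fell from 5523 to 2164 FPKM (log2 fold change -1.36), whereas STC2, a secreted glycoprotein, rose from 25.4 to 67.6 FPKM (1.38). The receptor tyrosine kinase gene RET rose by 0.97 on the log2 scale. The breast cancer stem cell list had 6 members that rose and 2 that fell out of 12, also adjusted over the list alone (camera adjusted p = 0.1), with CD24 at 0.80, MYC at 0.43 and KLF4 at -0.49. Of 18 genes of epithelial junctions and luminal identity 1 rose and 7 fell, and 2 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.1). No other tested list passed camera (adjusted p from 0.1 to 0.88). In the epithelial list AGR2, a disulfide isomerase of the endoplasmic reticulum, had -1.06 and the tight junction gene CLDN4 -0.50.

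Rises and falls are ranked here among called genes that met the filters of the naming rule. The genes with the largest rise besides PELP1 were H19, an imprinted noncoding RNA, with a log2 fold change of 2.21 ± 0.13 (SE), and the bradykinin receptor gene BDKRB2 with 2 ± 0.04. They were followed by the mitotic kinesin KIF20A (1.88), ANGPTL4 (1.73), FGD3 (1.67), HMMR (1.65), CD74 (1.62), CRISP3 (1.61) and RARRES3 (1.6). EMC10, a subunit of the endoplasmic reticulum membrane complex, showed the largest fall, from 19.7 ± 0.318 to 0.609 ± 0.145 FPKM (mean ± SD, n = 3), a log2 fold change of -3.69. Other large falls were those of the desmosomal gene PKP1 (-2.15), FAM101A (-2.13), S100P (-1.68), the actin capping gene CAPG (-1.66), MGP (-1.63), APOE (-1.6), NOV (-1.51), ST6GALNAC2 (-1.49) and PSCA (-1.44). CD74, the invariant chain of MHC class II, stood in the list of immune cell markers, in which the leukocyte antigen gene PTPRC stayed at 0.00903 FPKM or below in every group mean. Of 42 markers of immune, fibroblast, endothelial and basal keratinocyte cells in the table, 34 averaged below 1 FPKM in every group.

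In all, 4170 of 12032 tested genes changed between cytoPELP1 and LXSN, 1939 that rose and 2231 that fell (limma, adjusted p of 0.05), and 120 of them changed at least 2-fold on the log2(FPKM + 1) scale. The median log2 fold change of the changed genes was 0.33 in absolute size. Among genes of at least 50 FPKM 250 rose and 491 fell.

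The comparison of wtPELP1 with LXSN asked what the same amount of the wild-type protein's transcript went along with. PFKFB3 (7.19 FPKM against 7.49), PFKFB4 (3.35 against 3.08) and EPAS1 (0.86 against 0.999) did not pass the test, with log2 fold changes of -0.06, 0.09 and -0.10 (limma adjusted p = 0.64, 0.321 and 0.549). PGR (-0.08), ESR1 (0.17), NCOA1 (-0.10) and NCOA3 (-0.01) did not pass it either. HIF1A rose from 38.4 to 45.4 FPKM (log2 fold change 0.23, limma adjusted p = 0.00447), a call that ended with the trends on transcript length and GC content removed (0.15, adjusted p = 0.059). ESR1 passed only when the 6 libraries of both groups were fitted alone (adjusted p = 0.0118, and 0.023 with the replicate block).

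Interferon and cell cycle genes rose in wtPELP1 as a group. Of 26 type I interferon response genes 16 rose and 1 fell, and 18 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.8e-09, and 0.0093 with an estimated correlation), with IFI44L at 0.59 and DDX58, the RNA sensor RIG-I, at 0.53. Of 30 cell cycle genes 13 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 4.4e-06, and 0.028 with an estimated correlation), with the ubiquitin-conjugating gene UBE2C at 0.71 and cyclin A2, CCNA2, at 0.70. Hypoxia response genes went both ways: of 23 members 3 rose and 3 fell, and 4 rose and 4 fell adjusted over the list alone (median log2 fold change 0.03, camera adjusted p = 0.99). The glucose transporter gene SLC2A1 rose by 0.40, whereas NDRG1 had -0.72 and ERO1L -0.39. Of 18 glycolysis genes 3 rose and 3 fell, and 3 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.53), with PKM, pyruvate kinase, at -0.32. Of 16 PFKFB and other metabolic kinase genes 1 rose and 3 fell, and 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.32).

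A further 3 lists passed camera in wtPELP1 but not with an estimated correlation. Of 19 genes of the unfolded protein and integrated stress response 0 rose and 6 fell, and 1 rose and 7 fell adjusted over the list alone, with the transcription factor gene DDIT3 at -0.51 (camera adjusted p = 0.0062, but adjusted p = 0.6 with an estimated correlation). Of 43 ribosomal protein genes 2 rose and 0 fell, and 0 passed adjusted over the list alone (camera adjusted p = 0.0049, but adjusted p = 0.83 with an estimated correlation). With quantile normalization that call was lost and the list's direction turned downward (adjusted p = 0.56). Of 9 replication dependent histone genes 0 rose and 4 fell, and 5 fell adjusted over the list alone (camera adjusted p = 0.011, but adjusted p = 0.6 with an estimated correlation). The call of the histone list also ended without LXSN replicate 2 (adjusted p = 0.054). HIST1H2AC fell by 0.45 on the log2 scale, a call that ended without LXSN replicate 1 (limma adjusted p = 0.0506), wtPELP1 replicate 1 (0.0523) or wtPELP1 replicate 2 (0.0562). Estrogen response genes had 4 members that rose and 9 that fell out of 27, and 6 that rose and 9 that fell adjusted over the list alone (camera adjusted p = 0.32), RET at 0.94, IL20 at -0.84 and the amino acid transporter gene SLC7A5 at -0.68. No other tested list passed camera (adjusted p from 0.15 to 0.99).

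Rises and falls in wtPELP1 are ranked under the same filters. Besides PELP1, the largest rises in wtPELP1 were those of CRISP3 (log2 fold change 1.76), SPTSSB, a subunit of serine palmitoyltransferase (1.71), H19 (1.57), the neuroendocrine transcription factor gene ASCL1 (1.54), RBP5 (1.39), NELL2 (1.39), AMBP (1.32), CD74 (1.17) and KIF20A (1.14). SPTSSB went from 71.8 to 238.1 FPKM. The largest falls were those of MGST1, a microsomal glutathione transferase (-2.48), the solute carrier gene SLC5A8 (-2.42), BASP1 (-2.40) and CGA, the alpha chain of the glycoprotein hormones (-1.88). They were followed by CPB1 (-1.62), CSTA (-1.62), CAPG (-1.49), ARHGDIG (-1.44), the integrin gene ITGB5 (-1.35) and NPY1R (-1.31). KRT15, a keratin in the list of basal keratinocyte markers, rose from 6.06 to 12.7 FPKM (0.95), while KRT5 and KRT14 averaged below 0.1 FPKM in all 3 groups.

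In all, 1766 of 12032 tested genes changed between wtPELP1 and LXSN, 882 that rose and 884 that fell (limma, adjusted p of 0.05), and 57 of them changed at least 2-fold on the log2(FPKM + 1) scale. This count was 1125, 1058 and 1063 without LXSN replicate 1, 2 and 3 and 1135 without wtPELP1 replicate 2.

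The comparison of cytoPELP1 with wtPELP1 asked what went along with the place of PELP1 in the cell at a like level of its transcript. Here and against LXSN, other differences between the cell lines of the groups cannot be told apart from an effect of PELP1. PFKFB3 was higher in cytoPELP1 by a log2 fold change of 1.27 and PFKFB4 by 1.37 (limma adjusted p = 2.18e-06 and 5.17e-07). EPAS1 was higher by 1.27, and PGR lower, at -0.67 (limma adjusted p = 0.00141). HIF1A (0.08), NCOA1 (0.10) and NCOA3 (0.12) did not pass the test. ESR1 had -0.19 (limma adjusted p = 0.0446), a call that ended in 10 of the 17 alternatives run, including quantile normalization (-0.14, adjusted p = 0.219) and 5 of the 6 fits without a single library (adjusted p from 0.0838 to 0.129; without cytoPELP1 replicate 1 it held).

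Hypoxia response and metabolic kinase genes were higher in cytoPELP1 than in wtPELP1 as lists. Of 23 hypoxia response genes 21 were higher in cytoPELP1 and 0 lower, and 22 were higher adjusted over the list alone (median log2 fold change 1.07, camera adjusted p = 1.9e-26, and 0.004 with an estimated correlation). NDRG1, a hypoxia-induced gene, went from 9.77 ± 1.05 FPKM in wtPELP1 to 43.4 ± 2.26 FPKM in cytoPELP1 (mean ± SD, n = 3), a log2 fold change of 2.05, and ANGPTL4 was higher by 1.55. Of 18 glycolysis genes 14 were higher and 0 lower, and 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.5e-11, but adjusted p = 0.1 with an estimated correlation), with LDHA at 1.03 and ALDOC at 0.91. Of 16 PFKFB and other metabolic kinase genes 10 were higher and 1 lower, and 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 2e-06, and 0.013 with an estimated correlation).

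Cell cycle genes were higher in cytoPELP1 than in wtPELP1 for 20 of 30 members and lower for 0, and 24 were higher adjusted over the list alone (camera adjusted p = 1.9e-12, and 0.004 with an estimated correlation), TOP2A by 0.80 and MKI67 by 0.86. Of 26 interferon response genes 11 were higher and 0 lower, and 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00014, and 0.019 with an estimated correlation), MX2 by 0.54. Of 15 genes of fatty acid synthesis and storage 9 were higher and 2 lower, and 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 7.6e-05, and 0.037 with an estimated correlation). The lipid droplet coat gene PLIN2 was higher by 0.86 and ACSL3 by 0.64, and DGAT2 lower, at -0.62. Of 19 p53 target genes 1 was higher and 10 lower, and 1 higher and 12 lower adjusted over the list alone (camera adjusted p = 8.6e-05, and 0.019 with an estimated correlation), GDF15 at -0.77 and CDKN1A at -0.58.

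Another 6 lists passed camera between both PELP1 forms, each lost with an estimated correlation. Of 14 pentose phosphate and serine pathway genes 6 were higher and 0 lower, also adjusted over the list alone, led by PHGDH at 0.88 (camera adjusted p = 0.0021, but adjusted p = 0.31 with an estimated correlation). Of 19 genes of the unfolded protein and integrated stress response 7 were higher and 1 lower, and 8 higher and 2 lower adjusted over the list alone, with VLDLR at 0.74 (camera adjusted p = 0.0021, but adjusted p = 0.31 with an estimated correlation). Of 12 NRF2 antioxidant genes 4 were higher and 0 lower, and 4 higher and 1 lower adjusted over the list alone, with HMOX1, heme oxygenase 1, at 0.44 (camera adjusted p = 0.042, but adjusted p = 0.3 with an estimated correlation). Of 32 oxidative phosphorylation genes 2 were lower and 0 passed adjusted over the list alone (camera adjusted p = 0.004, but adjusted p = 0.64 with an estimated correlation). Of 18 genes of epithelial junctions and luminal identity 1 was higher and 6 lower, and 1 higher and 7 lower adjusted over the list alone, AGR2 at -0.41 (camera adjusted p = 0.035, but adjusted p = 0.13 with an estimated correlation). Of 5 basal and squamous keratinocyte markers 1, KRT15 at -0.95, was lower, and 2 were lower adjusted over the list alone (camera adjusted p = 0.03, but adjusted p = 0.31 with an estimated correlation). Single libraries decided 4 of these calls. Oxidative phosphorylation was lost without cytoPELP1 replicate 1 (adjusted p = 0.18), the epithelial list without wtPELP1 replicate 2 (0.081) or cytoPELP1 replicate 3 (0.064), the keratinocyte list without wtPELP1 replicate 2 (0.081), cytoPELP1 replicate 1 (0.072) or 3 (0.054), and the NRF2 list without wtPELP1 replicate 1 (0.085) or 2 (0.05) or cytoPELP1 replicate 3 (0.15). Quantile normalization ended the calls of oxidative phosphorylation (adjusted p = 0.32) and the epithelial list (0.72).

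Differences between both PELP1 forms are ranked under the same filters. Genes with the largest difference upward in cytoPELP1 were NDRG1, ANGPTL4, BASP1 (1.54), STC2 (1.54), BAMBI, a pseudoreceptor of the TGF-beta family (1.45), VTCN1 (1.37), PFKFB4, UCA1 (1.36), PFKFB3 and the mitophagy receptor gene BNIP3 (1.26). Those with the largest difference downward were EMC10 (-3.98), the cell adhesion gene CEACAM5 (-1.81), CALML5 (-1.68), AZGP1 (-1.54), CRABP1 (-1.51), TFF1 (-1.50), CEACAM6 (-1.45), the hair keratin gene KRT81 (-1.41), S100P (-1.35) and KIF12 (-1.34). In all, 2330 of 12032 tested genes differed, 1162 higher and 1168 lower in cytoPELP1 (limma, adjusted p of 0.05), and 62 of them differed at least 2-fold on the log2(FPKM + 1) scale. Among genes of at least 50 FPKM 137 were higher and 357 lower in cytoPELP1. Without wtPELP1 replicate 3 the count of all changed genes was 1417.

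**Figure D2:**
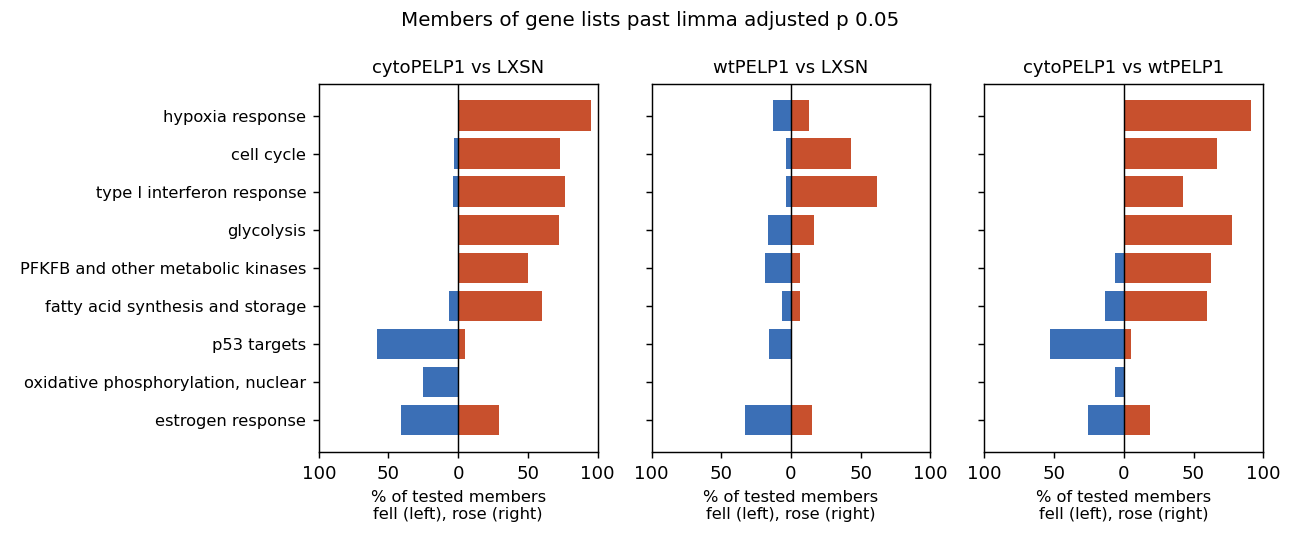
Share of the tested members of 9 gene lists (percent, horizontal axis) that rose (orange, to the right of 0) or fell (blue, to the left of 0) at a limma adjusted p of 0.05 in each of the 3 comparisons. In the hypoxia response list 22 of 23 members rose in cytoPELP1 against LXSN, and in wtPELP1 3 rose and 3 fell; the glycolysis and oxidative phosphorylation calls by camera were lost with an estimated correlation.

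The changes of both PELP1 forms against LXSN were then set side by side. CRISP3, H19, NELL2, CD74 and PELP1 rose in both, and CAPG, MGST1, NOV, CPB1 and PKP1 fell in both. CRISP3 rose by 1.61 in cytoPELP1 and by 1.76 in wtPELP1, and NELL2 by 1.28 and 1.39. MGST1 had log2 fold changes of -1.36 and -2.48, NOV of -1.51 and -1.31, CPB1 of -1.21 and -1.62, and PKP1 of -2.15 and -1.14. In total 593 genes rose in both and 552 fell in both, where independent lists of these lengths would share 142.1 and 163.9, and 77 genes were called in opposite directions. No expected number was computed for the opposite calls. In 100 simulations all libraries were drawn anew without any change, and both comparisons shared the 3 simulated LXSN libraries. At most 0 genes were then called in both. With no change planted few or no calls are expected in either comparison, so this count cannot show how much shared controls add to the overlap. The simulated libraries were drawn independently, so any pairing of LXSN and wtPELP1 libraries by number is absent from all simulated values. Part of the excess may come from the shared controls, since 3 libraries could not be split. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.43 against 0.50 in the simulations, and 72.7% had the same sign against 66.7%. Their covariance was 0.0514 against a simulated 0.0185, a difference of 0.0329. Over 8508 genes of at least 5 FPKM, without PELP1, small RNAs, uncharacterised loci and pseudogenes, a choice made after seeing the data, r was 0.62 against 0.50 in the simulations, and the covariance 0.0333 against 0.00293, a difference of 0.0303. The 1145 genes shared in the same direction became 733, 668 and 671 without LXSN replicate 1, 2 and 3.

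**Figure D3:**
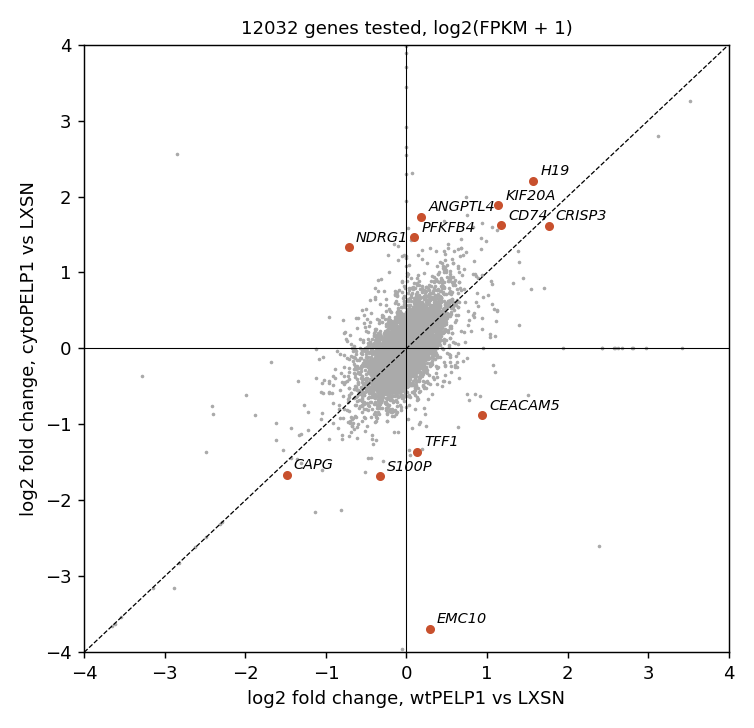
Log2 fold change on the log2(FPKM + 1) scale against LXSN in cytoPELP1 (vertical axis) and wtPELP1 (horizontal axis), 1 point per tested gene, with named genes in orange and equal change as a dashed line. CRISP3, CD74 and CAPG lie near the dashed line, EMC10 at -3.69 and PFKFB4 at 1.46 stand apart on the vertical axis, points exactly on an axis are mostly short RNAs listed at 0, and 20 genes, PELP1 among them, lie outside the axes.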

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

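The tests of depth, of length and GC content on the number of changed genes, and of the amount of PELP1 mRNA were chosen or extended only after the result was seen. A difference between both PELP1 forms marked 77 genes for a closer look: each passed limma against LXSN in both, in opposite directions, and passed the test of the difference itself. The model used the same spread for every comparison, so called changes in opposite directions all but fix the call of their difference. Passing that test in the main fit is thus no separate evidence. EMC10 was lower in cytoPELP1 than in wtPELP1 by the widest margin, with a log2 difference of -3.98. CEACAM5 (-1.81), CALML5 (-1.68), AZGP1 (-1.54), CEACAM6 (-1.45), KRT81 (-1.41), KIF12 (-1.34), FGFR3 (-0.89) and IGFBP5 (-0.70) were lower in cytoPELP1 and had risen in wtPELP1. NDRG1 (2.05), STC2 (1.54), BAMBI (1.45), VTCN1 (1.37), ERO1L (1.19), DUSP4 (0.98), ALDOC (0.91), PHGDH (0.88), PLIN2 (0.86), PKM (0.49) and HERC6 (0.45) were higher in cytoPELP1 and had fallen in wtPELP1. All 20 of these genes kept the call of the difference itself in each alternative, but not each call against LXSN. In wtPELP1 EMC10, STC2, ALDOC, IGFBP5, CALML5 and HERC6 lost it in 9, 9, 8, 7, 4 and 3 of 16 alternatives and BAMBI in 5 of 18, and in cytoPELP1 PKM in 8 and KRT81 in 1 of 17 and HERC6, PLIN2 and DUSP4 in 5, 4 and 2 of 15. Of the other genes of the 77, not run in this way, 5 (MYO1C, GEMIN4, ATP2A3, TSR1 and ANKFY1) were placed in a run of neighbouring genes lower in wtPELP1. These 5 may reflect that line rather than the PELP1 form. Genes without a place in the gene order used could not be assigned to the run, so more than 5 may lie in it.

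For the counts of changed genes, 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 4170 genes for cytoPELP1 against LXSN and the highest of the other splits 1. For wtPELP1 against LXSN these were 1766 and 1, also among the splits that part as many same-numbered pairs, and for cytoPELP1 against wtPELP1 2330 and 1. In each comparison 1 of the 10 splits, the real one, gave as many genes. The same splits are too few for the number of lists called by camera with the preset correlation: the real split gave 9, 5 and 13 lists and the highest other split 10, 3 and 12. As many lists as the real split came from 5, 1 and 1 of the 10 splits. Every other split mixes libraries of both groups unevenly and so keeps part of the group difference. Lists called there can hold some of that difference, so the splits cannot show how many lists are called without it. The p-values with an estimated correlation, planned beforehand, stand beside the calls of the real split and were not computed for the other splits.

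More genes changed against LXSN with cytoPELP1 than with wtPELP1, a ratio of 2.36. The excess was smaller when the 6 libraries of each comparison were fitted alone, each fit with its own spread. Then 3723 genes changed with cytoPELP1 and 2336 with wtPELP1. The deeper cytoPELP1 libraries were a candidate explanation, since depth lowers noise. The model of all 9 libraries took 1 spread per gene for every comparison, so lower noise in cytoPELP1 could not by itself favour its calls. Lower noise alone does not enlarge changes of abundant genes either. Among 1761 genes of at least 50 FPKM the median absolute log2 change was 1.58 times as large in cytoPELP1 (0.15 against 0.09), and 1.39 to 1.89 times without any 1 library. Of these genes 250 rose and 491 fell in cytoPELP1, and 172 rose and 124 fell in wtPELP1. A common downward shift of abundant genes in the cytoPELP1 libraries would also enlarge this measure, so it cannot exclude such a shift tied to depth. With length and GC trends removed the median absolute log2 change was 1.40 times as large (1.34 to 1.52 without any 1 library). The ratio of the counts was then 1.96 (1.43 to 2.58 without 1 library), lower than the 2.36 of all tested genes. By these measures neither lower noise nor these trends account for the pattern as a whole, though the trends may account for part of it. The ratio of the counts themselves moved from 1.36 to 3.63 without 1 library among abundant genes. A separate run or batch of the deeper cytoPELP1 libraries, or a difference in culture or harvest, none of which the labels describe, stays open. So does another difference between the cell lines, beside an effect of the PELP1 form.

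Hypoxia response genes were higher in cytoPELP1 than in wtPELP1. Trends on length and GC content could raise a list, but with them removed the median log2 change of its 22 members with such values was 1.04 against 1.05 before (camera adjusted p = 6.6e-26). Without any 1 library the median stayed at 1.01 or above, which argues against a single library, and wtPELP1, with as much PELP1 mRNA, had a median of 0.03 against LXSN, which argues against the amount of PELP1 mRNA. A response to cytoplasmic PELP1 is a hypothesis that may account for it. Larger or denser spheres with less oxygen in cytoPELP1, or a separate harvest or batch of the cytoPELP1 libraries, could do the same and were not tested, since sphere size and batches are not in the labels. Another difference between the cell lines could too and cannot be told apart from the PELP1 form.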

How the results depend on the processing

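Tests made for counts (DESeq2's and voom's models, their size factors, library totals) were not run because the table holds no counts. Counts of changed genes stayed within 1.5 times under pseudocount 0.1, no low value filter, quantile normalization, median scaling and the 6 libraries alone. The fit with a replicate block called 4089, 1704 and 2266 genes in place of 4170, 1766 and 2330, of which 3870, 1560 and 2083 were shared. The block ended the calls of HIST1H4H and EMC10 in wtPELP1 against LXSN and DGAT1 between both PELP1 forms, gave HIST1H2BK and the ribosomal protein list one there (adjusted p = 0.036 for the list, but adjusted p = 0.77 with an estimated correlation and no block), and changed no other call of a named gene or list in that fit of 9 libraries. In the 6 LXSN and wtPELP1 libraries alone 2336 genes were called without the block and 1751 with it, a fit added after seeing the data, 1635 of them in both and 1322 of the 1751 among the 1766. There the block ended the calls of PFKFB2, PER1, KLF4, TYMS, IKBKE, STC2 and HIST1H4H (adjusted p from 0.051 to 0.0857). ALDOC lost its call and ESR1, COX6C and COX7C gained one in these 6 libraries with or without it. Leaving out 1 library gave 2965 to 4335, 1058 to 1248 and 1417 to 2541 changed genes and 668 to 733 shared ones. Without cytoPELP1 replicate 3 the counts rose to 4335 and 2541; the cause was not tested. The lists called were then 9 to 10, 4 to 5 and 11 to 14, and PELP1's log2 fold changes 5.09 to 5.22 in cytoPELP1 and 5.09 to 5.24 in wtPELP1 against LXSN and -0.07 to 0.08 between them. Stricter thresholds and fewer genes also cut counts by construction: 120, 57 and 62 genes with a log2 fold change of at least 1, 459 shared genes at an adjusted p of 0.01, and 741, 296 and 494 among genes of at least 50 FPKM (775, 325 and 557 with the replicate block). Of these abundant genes 250 rose and 491 fell, 172 rose and 124 fell, and 137 were higher and 357 lower, a balance unlike that of all tested genes. Lists called numbered 5, 2 and 6 with an estimated correlation and 18 and 12 against LXSN with fry, which does not compare a list with other genes. OSGIN1's change in cytoPELP1 against LXSN, -0.18, became 0.01 with length and GC trends removed, with or without the block. The estrogen response list, not called by camera, was called upward by fry (adjusted p = 0.017); the ribosomal protein list turned downward in wtPELP1 against LXSN (adjusted p = 0.56) and upward between both forms (0.0089) with quantile normalization. The cause was not tested. Of 290 named gene results 218 kept their call and direction in each alternative. How depth limits calls of low genes was not tested.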

Other observations

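Some biology falls outside the comparisons above, and its genes were chosen after their values were seen. CA9, carbonic anhydrase 9, a hypoxia-induced gene of the cell surface, was listed at 0 in LXSN and averaged 0.0501 FPKM in wtPELP1 and 3.94 FPKM in cytoPELP1. VEGFA, another hypoxia response gene, stood at 53.2, 47.0 and 52.6 FPKM in LXSN, wtPELP1 and cytoPELP1 and did not pass limma in any comparison. The chemokine genes CCL2 and CCL5 rose in both PELP1 groups, CCL2 by 0.65 in wtPELP1 and 0.88 in cytoPELP1 and CCL5 by 0.49 and 0.59 (log2, against LXSN). BDKRB1, the neighbour and relative of BDKRB2, rose by 0.83 in cytoPELP1 and had 0.16 in wtPELP1, which did not pass. TFF3, a second trefoil peptide gene, rose from 69.6 FPKM to 151 FPKM in wtPELP1, where TFF1 had a log2 fold change of 0.13 that did not pass. KRT83 and KRT85, hair keratin genes close to KRT81, rose with it in wtPELP1 by 0.73 and 1.08, at group means below 3 FPKM and with reads that near copies may share, against 1.09 for KRT81.

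A run of neighbouring genes was lower in wtPELP1. It was found by sliding a window of 25 genes along the gene order of assembly GRCh38.p14, over 7973 genes of at least 5 FPKM, and the test of shuffled orders was chosen after the run was seen. Genes without a place in that order are not covered, so neighbours here are neighbours among the ordered genes. From RPH3AL to ALOX15, the genes next to PELP1 on one side, all 41 ordered genes had lower values in wtPELP1 than in LXSN and 40 passed limma, with a median log2 change of -0.39. In cytoPELP1 their median was -0.02 against LXSN, and the 41 genes on the other side of PELP1 had a median of -0.01 in wtPELP1. The run's median lay at -0.39, -0.39 and -0.38 in the wtPELP1 libraries and between -0.07 and 0.01 in the other 6. The widest window, GLOD4 to CLUH, had a median of -0.43, and 0 of 1000 shuffled orders held one as large (highest 0.21). With length and GC trends removed the run's median was -0.37, so neither chance order nor these trends accounts for it.

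Fewer copies of this region in the wtPELP1 line may be the cause. As a test written before its result was seen, 11 genes of the region below 5 FPKM, not used to find the run, were to have a median of -0.15 or below; they had -0.28, with 8 of 11 lower and 5 past limma's threshold. In cytoPELP1 against LXSN their median was -0.10, with 9 of 11 lower and 1 past the threshold, so the sign alone does not set wtPELP1 apart. This remains a hypothesis, since expression alone does not separate a loss of DNA from a regional loss of transcription, and the introduced PELP1 hides the level of the resident gene at the border of the run. Genes of this region that were called in wtPELP1 against LXSN, or as higher in cytoPELP1 than in wtPELP1 (36 of the 41, median 0.36), may then reflect the line and not PELP1, at least 5 of the 77 genes called in opposite directions among them.

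EMC10 fell from 19.7 to 0.609 FPKM in cytoPELP1 while 10 genes around it had a median log2 change of -0.16 against LXSN and none below -0.41. No explanation was tested. In cytoPELP1 against LXSN the widest window was MAF1 to COMMD5 with a median of -0.36, and EXOSC8 to LRCH1 with -0.37 once length and GC trends were removed, where 0 of 1000 shuffled orders held one as large in either fit.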
